A study of Homo sapiens with 12 samples.

How the data were processed

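RNA from HepG2 cells, an established human hepatoma line, was sequenced in 12 libraries, 3 each from cells given DMSO, 8HQ, FAC or 8HQ and FAC together (written 8HQ_FAC here). The labels give 10 µM and 6 h and name total RNA and Illumina library preparation. They do not say whether the 3 libraries of a group came from separate cultures, so every p-value measures only the spread between these samples, which may be technical. The replicate numbers in the titles were not taken as pairs.

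The authors deposited gene values as FPKM, that is fragments or reads per kilobase of gene or transcript model, scaled by the mapped total of the library, with 1 column per library. Per the submitters' processing notes, Bowtie 0.12.2 was used and the builds were mm8 and mm9. Those are mouse builds and cannot be the build of a human gene table, so no coordinates are given. The counter or quantifier, the annotation and the build behind the FPKM are not given in the sources used here. The analysis had first been laid out for read counts, and the FPKM form of the same layout was used because the deposited values are FPKM.

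The table listed 20030 genes with an NCBI GeneID each, of which 19741 matched a RefSeq gene table. A spreadsheet had turned 27 gene symbols into dates, and all 27 were restored through their GeneIDs. No pair of libraries was identical. Low values of a gene lay on multiples of a step that differed between libraries: of 24234 values below 0.3 FPKM in 2859 genes, 90.3% were within 0.05 of a whole multiple. The step of each gene was set from its own lowest value, which is thus a whole multiple by construction. The relative depths came from low values as well, so the share is no independent check. The steps gave each library's depth relative to DMSO replicate 1, from 0.773 to 1. Annotated transcript lengths of 2460 genes placed that library near 21700000 mapped fragments or reads, with quartiles of 19000000 and 29600000 across genes. At that depth 1 FPKM in a gene of 2 kb was 43 fragments or reads. Totals of mapped reads are not given in the sources used here, so no counting intervals were computed.

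Genes with at least 1 FPKM in at least 3 of the 12 libraries were tested, which were 10823 genes or 54.0% of those listed. Values were taken as log2 of FPKM plus a pseudocount of 1, which understates fold changes, most of all near or below 1 FPKM. Counts of genes past 2-fold use this scale. A model with 1 mean per group was fitted to all 12 libraries with limma 3.58.1 in R 4.3.3, with an intensity trend on the variance. Calls were made at a Benjamini-Hochberg adjusted p under 0.05, two-sided, within each of 6 comparisons. These were 5 comparisons of 2 groups and the interaction, which is the effect of FAC with 8HQ minus the effect of FAC without it. The sharing of calls between 2 comparisons was tested with Fisher's exact test. It takes genes as independent, which they are not, and the 2 comparisons share 1 variance per gene. A gene of small spread is thus more easily called in both, so the chance levels and p-values are rough guides. Correlations of log2 changes were computed across genes, which are not independent replicates. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

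Of 32 gene lists, the 29 with at least 5 tested members were tested with camera in limma, which compares a list with all other genes, at a preset correlation of 0.01, and adjusted p-values were computed over those lists in each comparison. The same test with a correlation estimated from the data and the rotation test fry were run beside it. For each list the members called over all tested genes are given with the count adjusted over the list alone. The lists covered iron, heme, copper and zinc handling, BMP-SMAD signalling, stress responses, lipid synthesis, the cell cycle, inflammation, liver functions, translation and respiration, and markers of other cell types.

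Genes were named by a fixed rule. It took a panel of 16 genes of iron metabolism and of responses to metals, of which 15 could be tested and ATOH8 was too low. It added the 6 genes that rose most and the 6 that fell most against DMSO and in the interaction, and 3 and 3 in the other comparisons. Those had at least 1 FPKM in the higher group and no overlap between the groups compared. It also took up to 4 members with the smallest adjusted p of each list described, and every gene of a count of 5 or fewer. The lists, the panel, the rule, the comparisons and the alternatives were fixed before the data were examined, except where another time is stated.

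The alternatives were quantile normalization, no filter, a filter at 5 FPKM, a pseudocount of 0.1, limma without the trend, only the 2 groups compared in the model, a replicate block, a test against a fold of 1.5 (treat), and leaving out each library in turn. Quantile normalization gives each gene the mean value of its rank across the libraries. A very abundant gene that keeps its rank therefore shows little or no change under it by construction. Added after the data were seen were median centring, a rescaling of each library to the same sum as in TPM, a fit without transcripts seen only in libraries without FAC, removal of a trend with transcript length, and 294 KEGG pathways taken from the annotation columns of the deposited table. The model was tested on simulated data of 10823 genes with 50 changed genes at each fold and the spread of these libraries. In the comparison of 8HQ with DMSO it recovered 46% of changes of 1.2-fold, 80% of 1.5-fold and 100% of 2-fold, and 5.8% of its calls were false. Left out were the table's text columns other than gene names and pathways.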

Results

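Transcript levels were measured by RNA sequencing in HepG2 cells, a human hepatoma line that makes many liver proteins. The 12 libraries formed 4 groups of 3, DMSO, 8HQ, FAC and 8HQ_FAC, with 10 µM and 6 h in the labels. It is not clear which agent the 10 µM refers to, since the same label puts it before DMSO. The letters are not spelled out; in work on iron, FAC usually stands for ferric ammonium citrate, an iron salt, and 8HQ for 8-hydroxyquinoline, which binds metals and can carry iron across membranes. The title of the series names labile iron inside cells and hepcidin, the liver hormone that limits iron export. Below, levels are mean FPKM ± SD with n = 3 libraries per group, and adjusted p-values come from the limma model over all tested genes.

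The FPKM of all genes summed to 337262 ± 2271 in DMSO, 338083 ± 2980 in 8HQ, 345776 ± 987 in FAC and 423226 ± 3959 in 8HQ_FAC. Sequencing depth relative to DMSO replicate 1 averaged 0.985 in DMSO, 0.955 in 8HQ, 0.957 in FAC and 0.806 in 8HQ_FAC, as estimated from the values, which is near 16700000 to 21700000 fragments or reads per library. The 10 most abundant genes held 8.07% of the sum in DMSO and 10.6% in 8HQ_FAC. The median tested gene lay at a log2 value of 3.40 in DMSO, 3.41 in 8HQ, 3.35 in FAC and 2.98 in 8HQ_FAC. Libraries of a group correlated across genes at r from 0.997 to 0.998.

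Transcripts of blood cells marked the libraries without FAC. HBB, a globin chain of red blood cells, stood at 0.421, 1.41 and 9.70 FPKM in the DMSO libraries and at 35.2, 6.97 and 1.52 in the 8HQ libraries. It was listed at 0 in all 6 libraries with FAC. Of 16 markers of leukocytes, Kupffer cells and red cells, 15 or 16 were above 0 in each DMSO and 8HQ library, 6 to 10 in the FAC libraries and 7 or 8 in the 8HQ_FAC libraries. TYROBP, a signalling adaptor of myeloid cells, and CD3E, a part of the T cell receptor, were listed at 0 in all 6 libraries with FAC and above 0 in the other 6. HLA-DRA and S100A8, chosen after their values were seen, showed the same. Of the 16 markers, 6 were above 0 in every library, among them LYZ at 1170 FPKM in DMSO replicate 3. In all, 133 genes were above 0 in at least 4 of the 6 libraries without FAC and at 0 in all 6 with it, against 53 the other way round. Other pairings of the groups gave 8 and 37 or 33 and 6. This split follows FAC exactly, so any separate handling of those libraries cannot be told apart from FAC in FAC vs DMSO, 8HQ_FAC vs DMSO and 8HQ_FAC vs 8HQ.

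**Figure D1:**
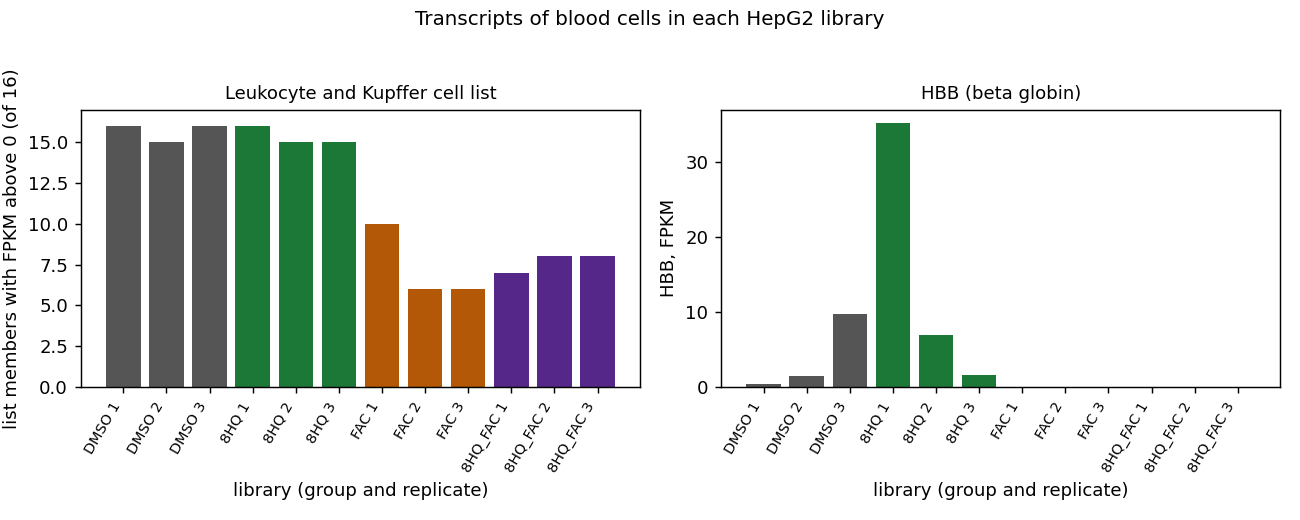
Number of the 16 markers of leukocytes, Kupffer cells and red cells with FPKM above 0 (left) and FPKM of HBB (right) in each of the 12 libraries, coloured by group. The libraries without FAC show 15 or 16 markers and the libraries with FAC 6 to 10, and HBB is listed at 0 in all 6 libraries with FAC.

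8HQ_FAC was compared with DMSO to ask what both agents together did to hepcidin and iron metabolism. HAMP, which encodes hepcidin, rose from 3.19 ± 0.81 to 31.1 ± 2.92 FPKM (n = 3 and 3, log2 change 2.95, SE 0.13, adjusted p = 8.12e-12). HMOX1, heme oxygenase 1, which breaks heme down and releases its iron, rose from 29.5 ± 0.579 to 227 ± 18.2. CYP1A1, a monooxygenase switched on by the aryl hydrocarbon receptor, fell from 88.5 ± 2.37 to 3.12 ± 0.172 (log2 change -4.44, adjusted p = 1.65e-19). SLC40A1, the iron exporter ferroportin, fell from 24.3 ± 1.2 to 13.7 ± 0.635. TMPRSS6, a protease that restrains hepcidin signalling, rose from 1.93 ± 0.125 to 3.11 ± 0.156. NDRG1, which responds to hypoxia and iron loss, rose from 10.6 ± 0.235 to 27.8 ± 1.04. The direction of these 6 genes was the same under quantile normalization, median centring, rescaling to equal sums and removal of the length trend.

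The median of all tested genes shifted by -0.23 on the log2 scale in this comparison, and relative to it HAMP stood 3.18 higher, HMOX1 3.13 higher and NDRG1 1.54 higher, SLC40A1 at -0.55 and CYP1A1 at -4.21. Several other panel genes turned with the scaling. The ferritin heavy chain gene FTH1 went from 1730 ± 34.7 to 2772 ± 50.5 FPKM, a log2 change of 0.68 that became -0.08 under quantile normalization. FTL, the ferritin light chain gene, rose from 3994 ± 109 to 6222 ± 72.3, a log2 change of 0.64 that was 0.12 under quantile normalization and with the length trend removed. For genes as abundant as FTH1 and FTL, quantile normalization holds changes small by construction while the rank is kept. Its values cannot decide in any comparison whether these 2 genes rose. TFRC, the transferrin receptor gene whose mRNA is stabilised when iron is low, went from 65.1 ± 1.39 to 47.2 ± 0.537; its log2 change of -0.46 became 0.02 with the length trend removed and was not called under median centring (-0.04, adjusted p = 0.313). ID1 and ID3, targets of BMP signalling, had log2 changes of -0.23 and -0.27 that became 0.18 and 0.14 under median centring. SMAD7 and TFR2 had log2 changes of 0.20 and 0.31 that became -0.08 and 0.00 with rescaling to equal sums, and MT1X, a metallothionein, had 0.80 that became 0.00 with the length trend removed. SMAD6, an inhibitor of BMP signalling, was not called (log2 change 0.12, adjusted p = 0.11), and was called higher under quantile normalization (0.40), median centring (0.54), removal of the length trend (0.46) and without DMSO replicate 2 (0.18).

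**Figure D2:**
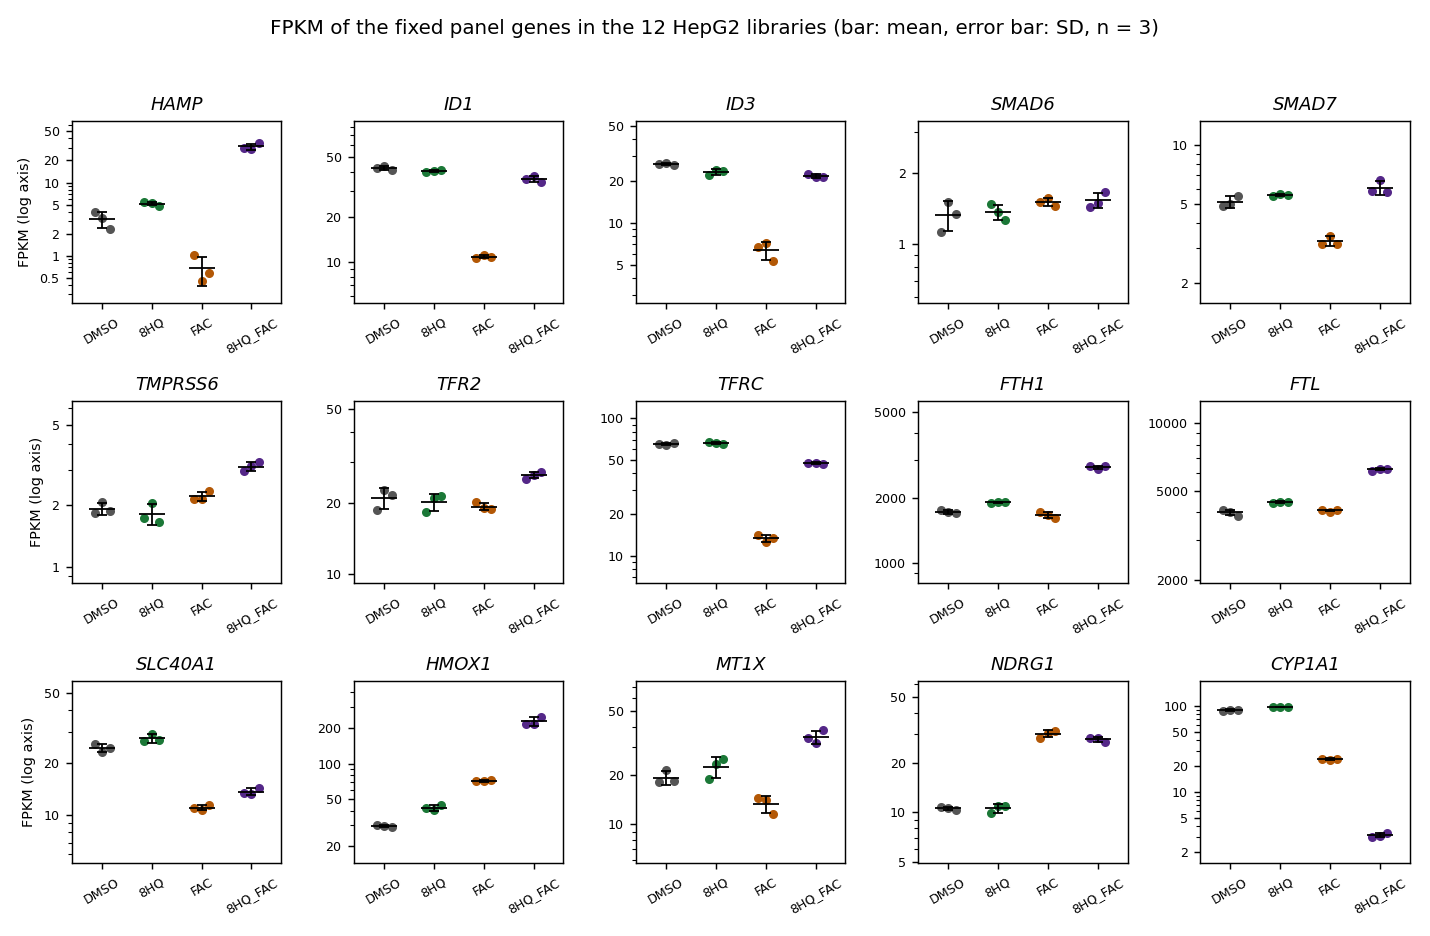
FPKM (log axis) of the 15 tested panel genes in each library by group, with bars at the mean and error bars of SD (n = 3). HAMP means run from 0.686 in FAC to 31.1 in 8HQ_FAC, while the direction of 8HQ_FAC vs DMSO turned under at least 1 scaling for FTH1, TFRC, ID1, ID3, SMAD7, TFR2 and MT1X.

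The genes with the largest rise from DMSO to 8HQ_FAC were SNAI1, a repressor of epithelial genes (1.27 ± 0.215 to 196 ± 13.5 FPKM), the immediate early genes FOS (2.56 ± 0.335 to 148 ± 5.67), ARC (0.18 ± 0.0798 to 36.8 ± 3.96) and FOSB (0.864 ± 0.0679 to 32.7 ± 2.2), RRAD, a small GTPase (1.05 ± 0.114 to 41.7 ± 3.43), and CA9, a carbonic anhydrase induced by hypoxia (1.31 ± 0.387 to 37.6 ± 2.96). Besides CYP1A1, the largest falls were in IGFBP1, which encodes a secreted binding protein of insulin-like growth factors (633 ± 17.2 to 63.1 ± 2.99), the Ras activator SOS1 (42.2 ± 0.567 to 5.45 ± 0.585), the MAP kinase phosphatase gene DUSP6 (61.8 ± 2.58 to 9.64 ± 0.856), DEPP1 (61.0 ± 0.169 to 9.72 ± 1.06) and the TGF-beta receptor gene TGFBR2 (86.3 ± 0.141 to 14.5 ± 0.774). In all, 9121 of 10823 genes were called, 2979 higher and 6142 lower, of which 240 and 1096 differed by at least 2-fold. The groups did not overlap for 9115 genes (84.2%, against 10% by chance). The calls that were higher made up 32.7% as deposited, 49.8% under quantile normalization, 63.3% under median centring, 15.7% with rescaling to equal sums and 50.7% with the length trend removed. The median shift under these was 0.00, 0.185, -0.497 and 0.005.

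Changes in 8HQ_FAC followed transcript length. Across the 10727 genes with a length in the annotation (99.1% of those tested), the longest annotated transcript and the log2 change from DMSO had a Spearman correlation of -0.52. Of 4 equal bins by length, the bin with the shortest transcripts had a median log2 change of 0.24 and 22.9% of its genes called lower. The bin with the longest had -0.63 and 83.5%. The correlation was -0.54 in 8HQ_FAC vs FAC, -0.52 in 8HQ_FAC vs 8HQ, -0.53 for the interaction, -0.12 in FAC vs DMSO and 0.00 in 8HQ vs DMSO.

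**Figure D3:**
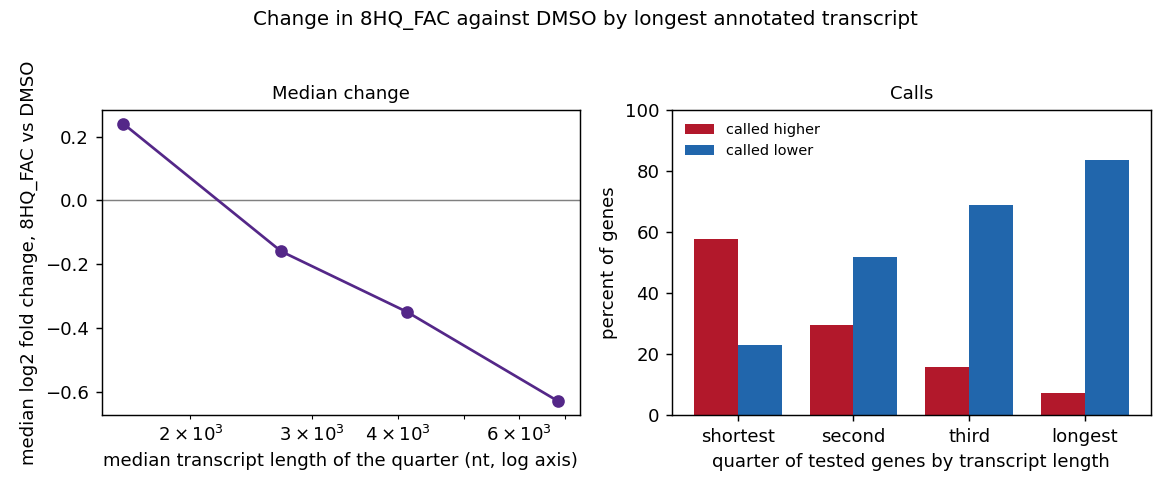
Median log2 change from DMSO to 8HQ_FAC against the median length of the longest annotated transcript (nt, log axis) in 4 equal bins of the tested genes (left), and the percent of each bin called higher or lower (right). The median log2 change runs from 0.24 in the shortest to -0.63 in the longest bin.

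Among the gene lists, HIF targets, which respond to low oxygen and to a loss of usable iron, rose in 8HQ_FAC against DMSO: 29 of 39 tested members were higher and 7 lower, also when adjusted over the list alone. Their median lay 0.84 above that of all genes on the log2 scale (adjusted p = 4.69e-09, and adjusted p = 0.00932 with an estimated correlation), and 0.67 to 0.89 above it under the 4 other scalings. Among them were the glycolysis genes ALDOA (295 ± 5.89 to 758 ± 7.92 FPKM) and ENO1 (484 ± 6.46 to 1088 ± 18.5) and the gene of the vessel peptide ADM (4 ± 0.333 to 54.7 ± 2.93). This was the only list of the 29 tested that was also called with an estimated correlation.

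The other lists called with the preset correlation lost the call with an estimated correlation, and the counts adjusted over the list alone equalled those over all genes unless given. Heat shock and proteotoxic response genes rose in 17 of 21 and fell in 2 (adjusted p = 9.25e-08, and adjusted p = 0.0715 with an estimated correlation), with the chaperone gene HSPA1B, which has a near copy in HSPA1A, going from 21.8 ± 0.421 to 154 ± 5.15 FPKM. Among the same genes BAG3 went from 17.2 ± 0.908 to 57.6 ± 3.93, and HSP90AB1 had a log2 change of 0.70 that became -0.01 under quantile normalization. All 36 cytosolic ribosomal protein genes rose (adjusted p = 4.41e-24, and adjusted p = 0.12 with an estimated correlation). Their median of 1.14 above that of all genes became 0.20 under quantile normalization, where very abundant genes that keep their rank change little by construction. Nuclear genes of oxidative phosphorylation rose in 27 of 30 and fell in 2 (adjusted p = 6.2e-11, and adjusted p = 0.126 with an estimated correlation), with COX5B, a subunit of cytochrome oxidase, at 221 ± 7.21 and 396 ± 22.0. Metallothioneins and zinc response genes rose in 7 of 10 and fell in 2 (adjusted p = 0.00608, and adjusted p = 0.102 with an estimated correlation), with MT1G at 22.7 ± 1.94 and 59.2 ± 4.09; this call was also lost under median centring (adjusted p = 0.0533) and with the length trend removed (adjusted p = 0.0944). Immediate early response genes rose in 14 of 21 and fell in 7, MYC among the latter from 46.9 ± 1.42 to 16.4 ± 0.448 (adjusted p = 0.00954, and adjusted p = 0.216 with an estimated correlation). That call was lost under quantile normalization (adjusted p = 0.0917), median centring (0.471) and removal of the length trend (0.293). NRF2 targets, genes of the response to oxidants, rose in 16 of 28 and fell in 8 (adjusted p = 0.002, and adjusted p = 0.247 with an estimated correlation; adjusted p = 0.872 under quantile normalization), with NFE2L2, the gene of NRF2 itself, at 109 ± 3.03 and 41.8 ± 2.62.

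Iron-sulfur cluster assembly genes were higher in 13 and lower in 7 of 25 (adjusted p = 0.0405, and adjusted p = 0.127 with an estimated correlation). Their call was lost under quantile normalization (0.0716), with rescaling to equal sums (0.192), with the length trend removed (0.293), with no filter (0.0966) and with a filter at 5 FPKM (0.0712). Acute phase and STAT3 response genes were higher in 8 and lower in 5 of 16 (adjusted p = 0.0469, and adjusted p = 0.126 with an estimated correlation). Their median less that of all genes turned to -0.21 under quantile normalization (0.103) and to -0.01 with the length trend removed (0.516). The call was also lost with rescaling to equal sums (0.211), no filter (0.0794), a filter at 5 FPKM (0.116), a pseudocount of 0.1 (0.0505), 2 groups in the model (0.0625), and without any of the 3 8HQ libraries (0.0517 to 0.0541) or 8HQ_FAC replicate 1 (0.0512). Replication-dependent histone genes, whose mRNA lacks a poly(A) tail, were higher in 8 and lower in 1 of 9 (adjusted p = 0.00156, and adjusted p = 0.12 with an estimated correlation). That call was lost under median centring (0.0533) and with the length trend removed (0.516). The 6 tested markers of leukocytes and Kupffer cells, 5 of them above 0 in every library, were higher in 4 and lower in 1 (adjusted p = 0.0405, and adjusted p = 0.126 with an estimated correlation). This call was lost under quantile normalization (0.322), median centring (0.258), removal of the length trend (0.465), no filter (0.666) and a pseudocount of 0.1 (0.0505).

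Lists nearest the study's question went both ways in 8HQ_FAC against DMSO and were not called. Of 16 BMP-SMAD targets and pathway genes, 6 were higher and 9 lower (adjusted p = 0.58); beside HAMP they held ID2, which rose from 36.4 ± 1.54 to 179 ± 9.75, and BMP4, which fell from 59.5 ± 1.9 to 20.2 ± 1.33. Of 19 genes of iron storage, uptake and export, 6 were higher and 11 lower (adjusted p = 0.708), with the transferrin gene TF at 829 ± 3.16 and 1888 ± 25.2 and LCN2, a siderophore-binding protein, at 17 ± 0.99 and 55.7 ± 2.96. The rotation test fry, which does not set a list against other genes, called both lists lower (adjusted p = 0.00122 and 0.0157), as it did 12 of the 29 in all. Elsewhere camera called the BMP-SMAD list higher. In 8HQ_FAC vs FAC 8 were higher and 5 lower (adjusted p = 0.0269, and adjusted p = 0.0853 with an estimated correlation). In the interaction 8 were higher and 5 lower (adjusted p = 0.0222, and adjusted p = 0.0708 with an estimated correlation). In FAC vs DMSO 2 were higher and 7 lower, without a call (adjusted p = 0.0508). These results were not followed under the other scalings. Heme synthesis and breakdown genes were higher in 7 and lower in 5 of 18, or 6 and 4 adjusted over the list alone (adjusted p = 0.16). Copper handling genes were higher in 9 and lower in 8 of 18 (0.106), and ferroptosis regulators higher in 6 and lower in 5 of 16 (0.114).

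The stress lists of ATF4 (9 higher and 19 lower of 31, adjusted p = 0.921), of the unfolded protein response (7 and 12 of 21, 0.667), of p53 (9 and 11 of 24, 0.28) and of NF-kB inflammation (6 and 7 of 13, 0.426) were not called, nor were AHR targets (2 and 4 of 6, 0.667), where CYP1A1 was the largest fall. In metabolism, the lists of cholesterol synthesis and uptake (6 and 12 of 23, 0.929), fatty acid and triglyceride synthesis (1 and 14 of 18, 0.135), PPARA targets and fatty acid oxidation (7 and 8 of 16, 0.356) and hepatocyte secretory and metabolic functions (14 and 14 of 28, 0.106) were not called. Neither were S phase genes (7 and 19 of 28, 0.325), G2 and M phase genes (6 and 23 of 29, 0.0936), dioxygenases that need iron and 2-oxoglutarate (6 and 23 of 31, 0.19) or cholangiocyte and kidney markers (3 and 3 of 6, 0.325). Some of these were called under another setting. G2 and M phase genes were called lower under quantile normalization (0.00476), with the length trend removed (0.00742) and with no filter (0.00506), and S phase genes lower under quantile normalization (0.00801). The dioxygenases were called lower under median centring (0.0455) and with no filter (0.0246), and fatty acid and triglyceride synthesis lower with rescaling to equal sums (0.0411) and with no filter (0.0246). Hepatocyte functions were called lower under quantile normalization (0.00812) but higher with rescaling to equal sums (0.00374), where copper handling was higher as well (0.0316). Of fibroblast and stellate cell markers 2 could be tested and 1 was higher, 0 endothelial markers could be tested, and 0 mitochondrially encoded transcripts were listed.

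**Figure D4:**
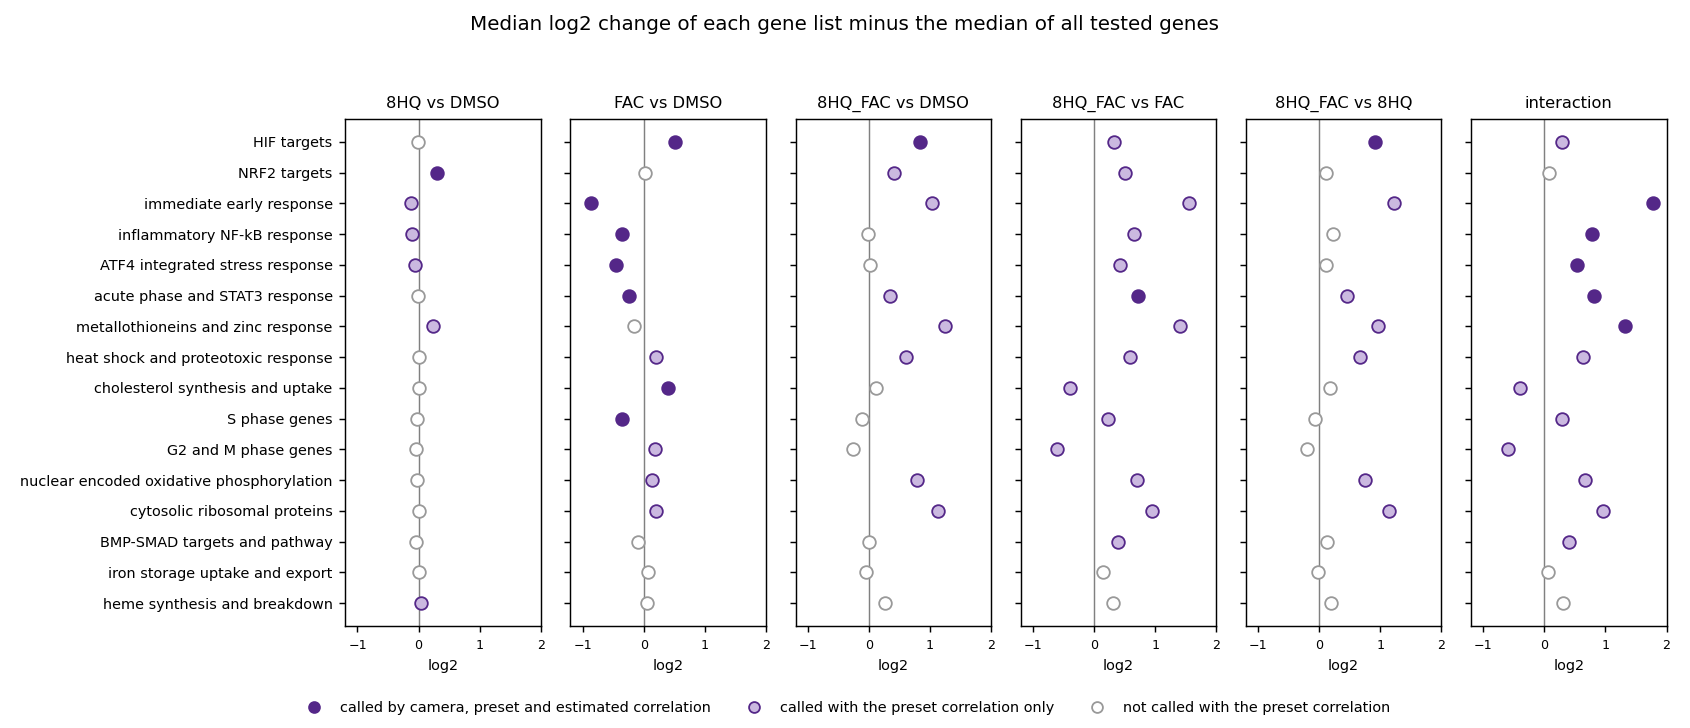
Median log2 change of 16 gene lists minus the median of all tested genes (x axis, log2) in the 6 comparisons, with filled points called by camera with both the preset and an estimated correlation, pale points with the preset correlation and open points not called. HIF targets lie at 0.52 in FAC vs DMSO and 0.84 in 8HQ_FAC vs DMSO, and NRF2 targets at 0.30 in 8HQ vs DMSO.

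8HQ was compared with DMSO to see what it did without added FAC, and both groups lie on the side with blood cell transcripts. NRF2 targets rose in 21 of 28 and fell in 1, or 25 and 1 adjusted over the list alone (adjusted p = 1.58e-39, and adjusted p = 0.00316 with an estimated correlation). The largest rises were in OSGIN1, a growth regulator induced by oxidants (37.8 ± 0.905 to 97.7 ± 1.38 FPKM, adjusted p = 6.63e-10), SRXN1, which repairs peroxiredoxins (63.1 ± 1.77 to 132 ± 2.04), the aldo-keto reductase gene AKR1B10 (29.9 ± 0.514 to 63.0 ± 2.63) and GCLM, a subunit of the first enzyme of glutathione synthesis (6.52 ± 0.188 to 14 ± 0.256). TXNRD1, thioredoxin reductase, went from 87.2 ± 1.08 to 151 ± 1.63, ABHD4 from 25.5 ± 1.75 to 47.1 ± 0.969 and UNKL from 4.64 ± 0.122 to 8.99 ± 0.402. HMOX1 rose from 29.5 ± 0.579 to 42.4 ± 2.34, FTH1 by a log2 change of 0.14 (adjusted p = 0.00326) and FTL by 0.15 (adjusted p = 0.000623).

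HAMP was higher with 8HQ, at 5.17 ± 0.283 against 3.19 ± 0.81 FPKM (log2 change 0.58, SE 0.13, adjusted p = 0.0186), but the call was lost without DMSO replicate 3 (0.0621), 8HQ replicate 1 (0.0645) or 8HQ replicate 2 (0.0588), with no filter (0.0859) and with a pseudocount of 0.1 (0.0654). Of the other panel genes, ID1, ID3, SMAD6, SMAD7, TMPRSS6, TFR2, TFRC, MT1X and NDRG1 were not called, and SLC40A1 and CYP1A1 had log2 changes of 0.17 and 0.11 (adjusted p = 0.054 and 0.0801). SLC40A1 was called under quantile normalization (0.0479), median centring (0.0485), a filter at 5 FPKM (0.0413) and without 8HQ_FAC replicate 3 (0.0448), where CYP1A1 was called as well (0.0487). ID3, with a log2 change of -0.19, was called without FAC replicate 3 (0.0203) and with 8HQ and DMSO alone in the model (0.031).

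Genes that fell with 8HQ were led by TCIM (26.2 ± 0.702 to 14.8 ± 0.854 FPKM), CBS, the first enzyme of transsulfuration (4.83 ± 0.503 to 2.52 ± 0.427), FILIP1L (18.0 ± 0.68 to 10.8 ± 0.179), ANKRD1 (32.7 ± 1.25 to 22.9 ± 0.294) and DEPP1 (61.0 ± 0.169 to 43.8 ± 0.919). EDN1, endothelin 1, had 2.80 ± 0.184 and 1.77 ± 0.456 and was no longer called without DMSO replicate 1 or 2, 8HQ replicate 1 or 3, with no filter or with a pseudocount of 0.1 (adjusted p from 0.0773 to 0.179). Immediate early genes fell in 6 of 21 and rose in 1, or 8 and 1 adjusted over the list alone (adjusted p = 0.000351, and adjusted p = 0.171 with an estimated correlation), with IER3 going from 148 ± 2.72 to 114 ± 4.96 and MYC up from 46.9 ± 1.42 to 56.4 ± 0.826. NF-kB response genes fell in 3 of 13, or 6 down and 1 up adjusted over the list alone (adjusted p = 0.000974, and adjusted p = 0.0562 with an estimated correlation). These were the chemokine gene CCL20 (269 ± 9.61 to 219 ± 6.73), NFKB1 (19.3 ± 0.415 to 16.7 ± 0.174), not called without DMSO replicate 1 (0.0503), and TNFAIP3, not called without DMSO replicate 1 or 2 or 8HQ replicate 2 or 3 (0.0833 to 0.0994).

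Metallothioneins and zinc response genes rose in 4 of 10 and fell in 1 with 8HQ (adjusted p = 0.0215, and adjusted p = 0.171 with an estimated correlation), led by the zinc exporter gene SLC30A1 (23.7 ± 0.795 to 28.7 ± 0.761 FPKM), MT1E, MT1F and MT1G. The list call was lost without DMSO replicate 3 (0.0696). The call of SLC30A1 was lost without DMSO replicate 1 (0.0503) or 8HQ replicate 1 (0.0545), and that of MT1E without DMSO replicate 2 (0.0624) or 8HQ replicate 1 (0.0545) or 2 (0.062) and with no filter (0.0623). MT1F was not called without DMSO replicate 1 (0.117) or 2 (0.0889) or 8HQ replicate 2 (0.059) or 3 (0.114), with no filter (0.102), with limma without the trend (0.0524) or with 2 groups in the model (0.0542). MT1G was not called without DMSO replicate 1 (0.0602) or 3 (0.103) or any of the 3 8HQ libraries (0.0616 to 0.102), with no filter (0.105) or with limma without the trend (0.0569). Heme genes rose in 4 of 18, or 5 up and 1 down adjusted over the list alone (adjusted p = 0.0371, and adjusted p = 0.388 with an estimated correlation): HMOX1, ALAS1, the first enzyme of heme synthesis (23.5 ± 0.364 to 28.8 ± 0.926), FECH, which puts iron into heme, and the heme transporter gene SLC48A1. That list call was lost without DMSO replicate 3 (0.0696), 8HQ replicate 1 (0.106) or 8HQ replicate 3 (0.161), with a filter at 5 FPKM (0.102) and with 2 groups in the model (0.0661). FECH was lost without DMSO replicate 1 (0.0676) or 8HQ replicate 1 (0.0632), and SLC48A1 without any of the 3 DMSO libraries (0.0689 to 0.106), 8HQ replicate 1 (0.0764) or 8HQ replicate 3 (0.152). SLC48A1 was also lost under quantile normalization (0.0653), with no filter (0.083), with a pseudocount of 0.1 (0.053) and with 2 groups in the model (0.0593). ATF4 targets (2 up and 3 down of 31, 4 and 4 adjusted over the list alone, adjusted p = 0.0142, and adjusted p = 0.225 with an estimated correlation; adjusted p = 0.056 with a filter at 5 FPKM) and AHR targets (2 up and 1 down of 6, 5 and 1 alone, adjusted p = 0.00916, and adjusted p = 0.204 with an estimated correlation) were the remaining lists called.

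With 8HQ, 531 genes were called, 270 higher and 261 lower, of which 3 rose by at least 2-fold on the scale with the pseudocount of 1, OSGIN1, SRXN1 and AKR1B10. GCLM, at 14 against 6.52 FPKM, fell just short on that scale. The count fell to 257 or 325 without DMSO replicate 1 or 2, and to 301, 338 or 289 without 8HQ replicate 1, 2 or 3. The higher share went from 50.8% to 37.6% with the length trend removed. The groups did not overlap for 2820 genes (26.1%, against 10% by chance).

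FAC was compared with DMSO to ask what it did without 8HQ, and separate handling of the FAC libraries cannot be told apart from it. HAMP fell from 3.19 ± 0.81 to 0.686 ± 0.293 FPKM (log2 change -1.31, adjusted p = 8.94e-07), at levels where the log2 change is understated. ID1 fell from 42.4 ± 1.26 to 10.9 ± 0.21, ID3 from 26.4 ± 0.434 to 6.37 ± 0.954 and SMAD7 from 5.14 ± 0.332 to 3.26 ± 0.177. TFRC fell from 65.1 ± 1.39 to 13.4 ± 0.736 (log2 change -2.20, adjusted p = 5.11e-15) and SLC40A1 from 24.3 ± 1.2 to 11.1 ± 0.38. HMOX1 rose from 29.5 ± 0.579 to 71.2 ± 0.985 and NDRG1 from 10.6 ± 0.235 to 30.1 ± 1.52, while CYP1A1 fell from 88.5 ± 2.37 to 23.9 ± 0.503 and MT1X from 19.3 ± 1.83 to 13.4 ± 1.62. FTL was not called (4077 ± 41.2, log2 change 0.03), but was called lower with the length trend removed (-0.06) and higher under quantile normalization (0.12) and median centring (0.08). FTH1 was not called either (1674 ± 53.5, -0.05), but was called lower under quantile normalization (-0.13), with rescaling to equal sums (-0.08), with the length trend removed (-0.10) and without FAC replicate 1 (-0.07). SMAD6, TMPRSS6 and TFR2 were not called; TMPRSS6 was called higher under median centring (adjusted p = 0.0218) and with the length trend removed (0.0427), and TFR2 lower without DMSO replicate 1 (0.0161).

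HIF targets rose with FAC in 31 of 39 and fell in 5 (adjusted p = 4.64e-13, and adjusted p = 0.00237 with an estimated correlation), with CA9 going from 1.31 ± 0.387 to 19.9 ± 0.813 FPKM and ALDOA from 295 ± 5.89 to 466 ± 7.43. SLC2A1, a glucose transporter gene of the same list, fell from 182 ± 4.41 to 98.8 ± 2.50. Other large rises were in PFKFB4, a regulator of glycolysis (0.914 ± 0.264 to 8.82 ± 0.425), LCN15 (1.66 ± 0.14 to 8.75 ± 0.381), MT1A (1.89 ± 0.141 to 8.44 ± 0.0521), the amino acid transporter gene SLC7A10 (0.568 ± 0.0435 to 3.92 ± 0.315) and SDHAF4, an assembly factor of succinate dehydrogenase (1.66 ± 0.582 to 6.73 ± 0.894). Cholesterol synthesis and uptake genes rose in 17 of 23 and fell in 3, or 18 and 3 adjusted over the list alone (adjusted p = 1.2e-07, and adjusted p = 0.0193 with an estimated correlation), such as MSMO1 (18.0 ± 1.42 to 47.9 ± 1.2) and SQLE, squalene epoxidase (36.3 ± 0.748 to 63.2 ± 1.46).

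Immediate early genes fell with FAC in 20 of 21 and rose in 0 (adjusted p = 1.32e-13, and adjusted p = 0.00607 with an estimated correlation), with the transcription factor gene EGR1 going from 21.6 ± 1.28 to 1.92 ± 0.0671 FPKM and IER3 from 148 ± 2.72 to 43.7 ± 1.59. ATF4 targets fell in 26 of 31 and rose in 2 (adjusted p = 1.12e-11, and adjusted p = 0.00607 with an estimated correlation), such as the stress cytokine gene GDF15 (280 ± 6.10 to 83.7 ± 1.01) and ASNS, asparagine synthetase (35.3 ± 1.26 to 11.5 ± 0.287). S phase genes fell in 26 of 28 and rose in 1 (adjusted p = 2.86e-11, and adjusted p = 0.00607 with an estimated correlation), with E2F1 at 59.5 ± 1.60 and 24.8 ± 1.10 and the replication clamp gene PCNA at 404 ± 8.77 and 303 ± 4.76. G2 and M phase genes went the other way, with 16 of 29 higher and 2 lower (adjusted p = 2.89e-05, and adjusted p = 0.0834 with an estimated correlation). NF-kB response genes fell in 10 of 13 (adjusted p = 1.16e-05, and adjusted p = 0.0075 with an estimated correlation), with CCL20 at 269 ± 9.61 and 139 ± 7.70. Acute phase genes fell in 12 of 16 and rose in 2 (adjusted p = 0.000286, and adjusted p = 0.0149 with an estimated correlation), with the protease inhibitor gene SERPINA3 at 992 ± 5.74 and 442 ± 6.53 and haptoglobin, HP, at 157 ± 3.38 and 98.6 ± 3.43. Other large falls were in CYP24A1, which degrades vitamin D (7.63 ± 0.365 to 0.919 ± 0.104), ANKRD1 (32.7 ± 1.25 to 6.82 ± 0.153) and ACTA1, skeletal muscle actin (20.4 ± 0.764 to 4.87 ± 0.413).

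Ribosomal protein genes rose in 32 of 36 with FAC (adjusted p = 2.86e-11, and adjusted p = 0.194 with an estimated correlation). In FAC vs DMSO, 5848 genes were called, 2689 higher and 3159 lower, of which 36 and 70 differed by at least 2-fold; the higher share was 46.0% as deposited and 38.3% to 59.0% under the other scalings. The groups did not overlap for 6647 genes (61.4%, against 10% by chance). The test for a change beyond 1.5-fold called 175.

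8HQ_FAC was compared with FAC to ask what 8HQ added where FAC was present, and both groups lie on the side without blood cell transcripts. HAMP rose from 0.686 ± 0.293 to 31.1 ± 2.92 FPKM (log2 change 4.26, SE 0.13, adjusted p = 2.63e-13). ID1 rose from 10.9 ± 0.21 to 35.9 ± 1.58, ID3 from 6.37 ± 0.954 to 21.7 ± 0.686, SMAD7 from 3.26 ± 0.177 to 6.06 ± 0.467, and TFRC from 13.4 ± 0.736 to 47.2 ± 0.537. HMOX1 rose from 71.2 ± 0.985 to 227 ± 18.2 and MT1X from 13.4 ± 1.62 to 34.5 ± 3.28, and CYP1A1 fell from 23.9 ± 0.503 to 3.12 ± 0.172. The median gene shifted by -0.22, and relative to it HAMP stood 4.47 higher, ID1 1.85 and TFRC 1.96. FTL had a log2 change of 0.61 that became 0.00 under quantile normalization, where FTH1, at 0.73, was no longer called (0.04, adjusted p = 0.327). Genes this abundant show almost no change there by construction while they keep their rank. The calls of TMPRSS6 (0.35), TFR2 (0.42) and SLC40A1 (0.28) were lost with rescaling to equal sums (adjusted p = 0.0689, 0.0592 and 0.812). SMAD6 was not called (0.01; -0.16 with rescaling to equal sums), but was called higher under median centring (0.38), quantile normalization (0.30) and removal of the length trend (0.32). NDRG1 was called (-0.11, adjusted p = 0.0491) but became 0.26 under median centring and 0.19 with the length trend removed. Its call was lost without FAC replicate 2 (0.122) or 3 (0.185), 8HQ_FAC replicate 2 (0.0545) or 3 (0.184), any of the 3 DMSO libraries (0.0535 to 0.0575), or 8HQ replicate 2 (0.0502) or 3 (0.0512). It was also lost under quantile normalization (-0.04, adjusted p = 0.524), with limma without the trend (0.0627), with no filter (0.0769) and with a pseudocount of 0.1 (0.0548).

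SNAI1 rose from 1.31 ± 0.335 to 196 ± 13.5 FPKM between FAC and 8HQ_FAC, FOS from 0.852 ± 0.40 to 148 ± 5.67 and ARC from 0.163 ± 0.0791 to 36.8 ± 3.96. Besides CYP1A1, DKK1, an inhibitor of WNT signalling, fell from 64.0 ± 2.62 to 10.8 ± 0.278 and C15orf39 from 16 ± 0.559 to 2.21 ± 0.104. Acute phase genes rose in 12 of 16 and fell in 2 (adjusted p = 8.94e-06, and adjusted p = 0.0237 with an estimated correlation; adjusted p = 0.372 under quantile normalization), with SERPINA3 going from 442 ± 6.53 to 772 ± 16.2. SERPINA1, alpha 1 antitrypsin, had a log2 change of 0.64 that became -0.14 under quantile normalization. G2 and M phase genes fell in 26 of 29 and rose in 1 (adjusted p = 0.000313, and adjusted p = 0.0859 with an estimated correlation), such as the proliferation marker MKI67 (46.2 ± 0.797 to 14.6 ± 0.668) and TOP2A, topoisomerase 2 alpha (150 ± 3.52 to 62.4 ± 2.23). Cholesterol genes fell in 19 of 23 and rose in 3 (adjusted p = 0.00887, and adjusted p = 0.146 with an estimated correlation), with SQLE at 63.2 ± 1.46 and 19.6 ± 1.25. All 36 ribosomal protein genes rose (adjusted p = 1.11e-23, and adjusted p = 0.0624 with an estimated correlation), RPL10A from 709 ± 2.63 to 1172 ± 12.9. Replication-dependent histone genes rose in 7 of 9 and fell in 0 (adjusted p = 2e-04, and adjusted p = 0.0574 with an estimated correlation; adjusted p = 0.151 with the length trend removed). Leukocyte and Kupffer cell markers rose in 5 of 6 and fell in 0 (adjusted p = 0.00819, and adjusted p = 0.0591 with an estimated correlation), a call lost under quantile normalization (0.0904), median centring (0.103) and removal of the length trend (0.149). In all, 8968 genes were called, 2905 higher and 6063 lower. The higher share was 32.4% as deposited and 15.6% to 62.6% across the scalings. The groups did not overlap for 9043 genes (83.6%, against 10% by chance).

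8HQ_FAC was compared with 8HQ to ask what FAC added where 8HQ was present, where the split by blood cell transcripts again follows FAC. HAMP rose from 5.17 ± 0.283 to 31.1 ± 2.92 FPKM (log2 change 2.38, SE 0.13, adjusted p = 9.81e-11), HMOX1 from 42.4 ± 2.34 to 227 ± 18.2, NDRG1 from 10.6 ± 0.635 to 27.8 ± 1.04, and TMPRSS6 from 1.82 ± 0.217 to 3.11 ± 0.156. SLC40A1 fell from 27.5 ± 1.48 to 13.7 ± 0.635 and CYP1A1 from 95.9 ± 0.37 to 3.12 ± 0.172. HIF targets rose in 28 of 39 and fell in 6 (adjusted p = 3.82e-09, and adjusted p = 0.00901 with an estimated correlation), with CA9 at 1.38 ± 0.335 and 37.6 ± 2.96 and ADM at 5.16 ± 0.787 and 54.7 ± 2.93. All 36 ribosomal protein genes rose (adjusted p = 2.38e-24, and adjusted p = 0.102 with an estimated correlation), RPS2 from 1784 ± 56.7 to 3642 ± 110. Replication-dependent histone genes rose in 8 of 9 and fell in 1 (adjusted p = 0.00111, and adjusted p = 0.102 with an estimated correlation), a call lost under median centring (0.0507) and with the length trend removed (0.56). Leukocyte and Kupffer cell markers, higher in 4 and lower in 1 of 6, lay at the threshold (adjusted p = 0.05, and adjusted p = 0.131 with an estimated correlation). SNAI1 rose from 1.43 ± 0.176 to 196 ± 13.5, FOS from 2.55 ± 0.0601 to 148 ± 5.67 and ARC from 0.0939 ± 0.039 to 36.8 ± 3.96, and IGFBP1 fell from 536 ± 6.25 to 63.1 ± 2.99. HBB was also among the largest falls, with the values per library given with the blood cell transcripts.

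The median gene shifted by -0.25 between 8HQ and 8HQ_FAC. TFRC had a log2 change of -0.48 that became 0.01 with the length trend removed and was not called under median centring (-0.06, adjusted p = 0.165). FTH1 had 0.54 that became -0.29 under quantile normalization, FTL 0.49 that became -0.15 there and -0.01 with the length trend removed, and MT1X 0.60 that became -0.20 with the length trend removed. ID1 had -0.18 that became 0.24 under median centring. The call of TFR2 (0.36) was lost with rescaling to equal sums (adjusted p = 0.497). ID3, SMAD6 and SMAD7 were not called (-0.09, 0.10 and 0.11). ID3 became 0.34 under median centring and was called lower with rescaling to equal sums (-0.40) and with the length trend removed (-0.39). SMAD7 became -0.17 with rescaling to equal sums and was called higher under the other scalings. SMAD6 was called higher under quantile normalization, median centring and removal of the length trend (0.40 to 0.52). In all, 9139 genes were called, 2900 higher and 6239 lower. The higher share was 31.7% as deposited and 15.4% to 62.3% across the scalings. The groups did not overlap for 9167 genes (84.7%, against 10% by chance).

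The interaction asked whether the effect of FAC differed with and without 8HQ, and a handling effect that adds equally to all libraries with FAC cancels in it. A bias of the 8HQ_FAC libraries alone does not cancel, and the changes in the interaction followed transcript length (Spearman correlation -0.53). HAMP fell with FAC alone and rose with FAC when 8HQ was present, a difference of 3.68 on the log2 scale (SE 0.18, adjusted p = 1.7e-10). The difference was 1.69 for ID1, 1.82 for ID3, 0.64 for SMAD7, 1.73 for TFRC, 1.15 for HMOX1, 1.10 for MT1X and -2.71 for CYP1A1, all called and of the same direction under the 4 other scalings. FTH1 and FTL had 0.58 and 0.46, which became -0.16 and -0.27 under quantile normalization, and FTL was not called with the length trend removed (0.05, adjusted p = 0.219). TMPRSS6 (0.41) and TFR2 (0.47) were called but not with rescaling to equal sums (adjusted p = 0.0692 and 0.0735). SMAD6 (-0.02), SLC40A1 (0.11) and NDRG1 (-0.10) were not called. SMAD6 became 0.36, 0.29 and 0.31 under median centring, quantile normalization and removal of the length trend. SLC40A1 was called higher under those same settings (0.35 to 0.48). NDRG1 became 0.27 under median centring and 0.21 with the length trend removed, and was called lower with rescaling to equal sums (-0.38) and without 8HQ replicate 1 (-0.15). The median gene stood at -0.24, and relative to it HAMP was at 3.92 and TFRC at 1.96.

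In the interaction, immediate early genes were higher in 15 of 21 and lower in 5 (adjusted p = 2.52e-07, and adjusted p = 0.0436 with an estimated correlation). The differences were 6.35 for FOS, 4.76 for FOSB, 4.13 for EGR1, 4.23 for ATF3 and 3.05 for IER3. EGR1 stood at 21.6 ± 1.28 FPKM in DMSO, 18.1 ± 0.311 in 8HQ, 1.92 ± 0.0671 in FAC and 42.2 ± 2.91 in 8HQ_FAC. SNAI1, ARC and HBEGF, a ligand of the EGF receptor, had differences of 6.32, 5.13 and 4.52. ATF4 targets were higher in 22 of 31 and lower in 8 (adjusted p = 2.83e-05, and adjusted p = 0.0436 with an estimated correlation), with 1.92 for GDF15 and 1.28 for ASNS. NF-kB response genes were higher in 9 of 13 and lower in 3 (adjusted p = 0.000132, and adjusted p = 0.0395 with an estimated correlation), with 2.54 for the chemokine gene CXCL8 and 1.66 for NFKBIA. Metallothioneins and zinc response genes were higher in 7 of 10 and lower in 2 (adjusted p = 0.00151, and adjusted p = 0.0436 with an estimated correlation; adjusted p = 0.0613 with the length trend removed), with 1.54 for MT2A and -1.36 for the zinc importer gene SLC39A10. Acute phase genes were higher in 11 of 16 and lower in 2 (adjusted p = 8.98e-07, and adjusted p = 0.0136 with an estimated correlation; adjusted p = 0.229 under quantile normalization). Among these SERPINA3 had 0.77 and SOCS3, a feedback inhibitor of STAT3, 1.77, while SERPINA1 and FGG, at 0.62 and 0.58, became -0.26 and -0.03 under quantile normalization. Replication-dependent histone genes were higher in 7 of 9 and lower in 0 (adjusted p = 0.000132, and adjusted p = 0.0532 with an estimated correlation; adjusted p = 0.171 with the length trend removed). Leukocyte and Kupffer cell markers were higher in 4 of 6 and lower in 0, or 3 and 0 adjusted over the list alone (adjusted p = 0.0147, and adjusted p = 0.0674 with an estimated correlation). That call was lost under quantile normalization (0.0846), median centring (0.139) and removal of the length trend (0.206).

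Among the largest negative differences after CYP1A1 were those of C15orf39 (-2.36), TGFBR2 (-2.19), the WNT target SP5 (-2.11) and DKK1 (-2.07). TGFBR2 stood at 86.3 ± 0.141 FPKM in DMSO, 75.4 ± 1.54 in 8HQ, 79.8 ± 0.233 in FAC and 14.5 ± 0.774 in 8HQ_FAC. In all, 8303 genes were called in the interaction, 2533 higher and 5770 lower. The higher share was 30.5% as deposited and 14% to 62.3% across the scalings.

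The effect of FAC was set against that in the presence of 8HQ across all tested genes. Called in both were 3734 genes in the same direction, 1295 higher and 2439 lower, where 720.5 and 1821 would be shared by chance. Both comparisons set libraries with FAC against libraries without it. Any handling that follows FAC would thus add to the shared calls and cannot be told apart from FAC here. The balance of higher and lower turned with the scaling, with 1874 and 1858 under quantile normalization, 2571 and 1349 under median centring, 719 and 3284 with rescaling to equal sums and 1906 and 1811 with the length trend removed, each above its chance level. Another 940 were higher with FAC alone and lower with FAC in the presence of 8HQ, and 375 the other way round, fewer than the 1550.1 and 846.4 by chance. HMOX1, NDRG1 and CA9 rose in both, SLC40A1, IGFBP1 and CYP1A1 fell in both, and HAMP was among the 375. The Pearson correlation across genes was 0.39 and the Spearman correlation 0.41. For the effect of 8HQ without and with FAC, 249 genes were called in the same direction, 80 higher (72.5 by chance, Fisher's exact p = 0.297) and 169 lower (146.2 by chance, p = 0.00442). Another 142 were higher with 8HQ alone and lower with 8HQ in the presence of FAC, and 72 the other way round, against 151.3 and 70.1 by chance. These chance levels take genes as independent, while both comparisons share 1 variance per gene. The shared falls were also beyond chance by Fisher's exact test under quantile normalization (192 against 130, p = 2.02e-12), median centring (128 against 84.8, p = 4.55e-08) and removal of the length trend (183 against 146.7, p = 0.000166). With rescaling to equal sums they were not (208 against 197.1, Fisher's exact p = 0.149), and the shared rises were (52 against 33.2, Fisher's exact p = 0.000873). The correlations were 0.05 and 0.01. HMOX1 and HAMP rose in both. The 249 became 136 or 156 without DMSO replicate 1 or 2, and 144 or 138 without 8HQ replicate 1 or 3.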

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

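The regrouping test in this part was set beforehand, and no test in it was chosen only after the result was seen. The results below are here because the effect of FAC differed between cells given 8HQ and cells not given it, by a test of that difference itself. The effect differed for 8303 genes. A bias of the 8HQ_FAC libraries alone, such as with transcript length (Spearman correlation -0.53 in the interaction), would also count as such a difference. On the log2 scale the effect with 8HQ minus the effect without it was 3.68 for HAMP, 1.73 for TFRC, 1.69 for ID1, 4.13 for EGR1, -2.71 for CYP1A1, 1.15 for HMOX1 and 6.32 for SNAI1. Of 100 groupings of the 12 libraries into 4 groups of 3, drawn with a fixed seed and counting the real one, 1 called as many genes. That argues against no difference between any of the groups. Regrouping also breaks up the effects of each agent, so it cannot show by itself that the effects of FAC differ. The highest other grouping called 7385, which points to a structure of the samples such as the groups themselves. No single library was tested for lying far from the others, since the groups hold 3.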

How the results depend on the processing

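Chosen only after the data were seen were median centring, rescaling to equal sums, removal of the length trend and the fit without trace transcripts, while the other settings were set beforehand. Over all settings, 5963 values of named genes kept their side of the threshold and, where called, their direction. Without turning, 142 lost the call and 42 gained it. Another 31 turned direction and were called in at least 1 of the 2 fits set against each other. For the list results followed through the settings these numbers were 1356, 90, 19 and 8. BMP-SMAD targets outside 8HQ_FAC vs DMSO were not among them, nor were HIF targets in 8HQ_FAC vs FAC and the interaction. Where a value changed below, the cause was not tested unless stated. The spread between 3 libraries set limits too. In simulated data with that spread and 50 changed genes at each fold, 46% of changes of 1.2-fold were recovered in 8HQ vs DMSO. For 8HQ_FAC vs DMSO it was 56% and for the interaction 32%, against 80%, 88% and 78% at 1.5-fold in this order. Far more genes were called in the real 8HQ_FAC vs DMSO (84.3%) and interaction (76.7%), which makes the adjusted threshold less strict there. The simulated recovery for those comparisons is therefore not that of the real data. The 8HQ_FAC libraries were the shallowest, with relative depths of 0.773, 0.803 and 0.842, and no simulation varied depth.

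In the order 8HQ_FAC vs DMSO, 8HQ vs DMSO, FAC vs DMSO, 8HQ_FAC vs FAC, 8HQ_FAC vs 8HQ and the interaction, the counts of called genes were 9121, 531, 5848, 8968, 9139 and 8303. They were 8853, 617, 5859, 8610, 8882 and 7622 under quantile normalization and 9134, 519, 6021, 8851, 9145 and 8068 under median centring. Rescaling to equal sums gave 9449, 519, 5960, 9298, 9483 and 8709, and removal of the length trend 8599, 639, 5929, 8227, 8618 and 7280. No filter gave 10381, 381, 5987, 9993, 10434 and 8865, and a filter at 5 FPKM 6866, 541, 4578, 6793, 6831 and 6359, with more or fewer genes tested. A pseudocount of 0.1 gave 9104, 491, 5774, 8965, 9124 and 8269, limma without the trend 9091, 474, 5809, 8959, 9117 and 8262, and the fit without trace transcripts 9119, 531, 5849, 8968, 9139 and 8303. With only the compared groups in the model the first 5 counts were 9037, 420, 5863, 8944 and 9118.

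The test for a change beyond 1.5-fold, stricter by its construction, called 2924, 5, 175, 2244, 3004 and 1894 genes, of which 636, 5, 67, 365, 622 and 279 were higher. The 5 in 8HQ vs DMSO were OSGIN1, SRXN1, AKR1B10, GCLM and TXNRD1. It left 97 genes called in the same direction for the effect of FAC with and without 8HQ, and 1, SRXN1, for the effect of 8HQ.

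Leaving out 1 library at a time gave 8873 to 9110 calls in 8HQ_FAC vs DMSO, 257 to 564 in 8HQ vs DMSO, 5274 to 5921 in FAC vs DMSO, 8685 to 8977 in 8HQ_FAC vs FAC, 8907 to 9144 in 8HQ_FAC vs 8HQ and 8097 to 8218 in the interaction. The 257 came without DMSO replicate 1. The lists called numbered 10 to 11, 6 to 8, 15 to 16, 20 to 22, 9 to 10 and 19 to 20. Of the list calls, that of leukocyte and Kupffer cell markers in 8HQ_FAC vs 8HQ was lost without DMSO replicate 1 or 3, any of the 3 8HQ libraries, FAC replicate 2 or 8HQ_FAC replicate 3 (adjusted p from 0.0501 to 0.0681), and under quantile normalization (0.178), median centring (0.293), removal of the length trend (0.544), no filter (0.702) and a pseudocount of 0.1 (0.0658). The sharing of calls was 3407 to 3718 for FAC and 136 to 260 for 8HQ, and the correlations were 0.38 to 0.40 and 0.01 to 0.08.

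Under quantile normalization, FTH1 turned to -0.08 and HSP90AB1 to -0.01 in 8HQ_FAC vs DMSO, FTL to 0.00 and SERPINA1 to -0.14 in 8HQ_FAC vs FAC, and FTH1 to -0.29 and FTL to -0.15 in 8HQ_FAC vs 8HQ. In the interaction SMAD6 turned to 0.29, FTH1 to -0.16, FTL to -0.27, SERPINA1 to -0.26 and FGG to -0.03. For very abundant genes such as FTH1 and FTL, small changes under this setting come in part by construction. The correlation for the effect of 8HQ moved from 0.05 to 0.07. Under median centring, ID1 turned to 0.18 and ID3 to 0.14 in 8HQ_FAC vs DMSO, NDRG1 to 0.26 in 8HQ_FAC vs FAC, and ID1 to 0.24 and ID3 to 0.34 in 8HQ_FAC vs 8HQ. There the interaction turned to 0.36 for SMAD6 and 0.27 for NDRG1.

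With rescaling to equal sums, SMAD7 turned to -0.08 and TFR2 to 0.00 in 8HQ_FAC vs DMSO, SMAD6 to -0.16 in 8HQ_FAC vs FAC and SMAD7 to -0.17 in 8HQ_FAC vs 8HQ. The correlation for the effect of FAC went from 0.39 to 0.40, to 0.38 with no filter and to 0.37 with a pseudocount of 0.1. With the length trend removed, TFRC turned to 0.02 and MT1X to 0.00 in 8HQ_FAC vs DMSO, FTL to -0.06 in FAC vs DMSO and NDRG1 to 0.19 in 8HQ_FAC vs FAC. TFRC turned to 0.01, FTL to -0.01 and MT1X to -0.20 in 8HQ_FAC vs 8HQ, and SMAD6 to 0.31 and NDRG1 to 0.21 in the interaction.

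The gene lists called were 11, 7, 15, 20, 10 and 20 in the order above. An estimated correlation, which widens the test by its construction, left 1, 1, 7, 1, 1 and 5. With the length trend removed, 6 were called in 8HQ_FAC vs DMSO and 5 in 8HQ_FAC vs 8HQ, and with a filter at 5 FPKM 7 and 6. In these comparisons all 11 and all 10 lists had been called higher; quantile normalization called 6 higher and 3 lower in 8HQ_FAC vs DMSO, and 4 higher and 5 lower in 8HQ_FAC vs 8HQ, and no filter 8 and 3, and 6 and 3. Under quantile normalization acute phase genes turned to -0.21 and hepatocyte functions to -0.33 in 8HQ_FAC vs DMSO. The rotation test fry, which does not compare a list with other genes, called 26 in 8HQ_FAC vs DMSO, 24 in FAC vs DMSO and 25 in 8HQ_FAC vs 8HQ. In 8HQ_FAC vs DMSO it called iron storage, uptake and export (adjusted p = 0.0157) and BMP-SMAD targets (adjusted p = 0.00122) lower, where camera had leaned higher without a call. The same held for the unfolded protein response, cholesterol synthesis and uptake, PPARA targets and hepatocyte functions. The medians of these 6 lists less that of all genes were -0.04, 0.01, 0.13, 0.12, 0.10 and 0.12 in both tests.

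The replicate numbers did not pair the libraries: in 18 pairs with the same number r ran from -0.076 to 0.048, and 4 of 12 libraries lay closest to one of their own number. With the number as a block the counts were 9107, 450, 5756, 8941, 9117 and 8305. Of the named genes NDRG1 lost its call in 8HQ_FAC vs FAC (adjusted p = 0.0565) and ICAM1 gained 1 in 8HQ vs DMSO (0.0432), and acute phase genes lost theirs as a list in 8HQ_FAC vs DMSO (0.0544), as did leukocyte and Kupffer cell markers in 8HQ_FAC vs 8HQ (0.0526). It changed no other call of a gene or list followed through the settings, and 10, 7, 16, 20, 9 and 20 lists were called.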

Other observations

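Chosen only after the result was seen were the tests on pathways, on median centring, on long abundant transcripts, on the blood cell transcripts and on HIF targets. KEGG pathways named in the deposited table, 294 in all, were tested on the values as deposited and under no other scaling. Some share genes with the lists above, such as histones, and others hold gene groups that the lists did not. Between DMSO and 8HQ_FAC, Proteasome genes rose in 32 of 42 and fell in 6 (adjusted p = 2.78e-07, and adjusted p = 0.14 with an estimated correlation). Glutathione metabolism rose in 28 of 41 and fell in 7 (adjusted p = 7.95e-07, and adjusted p = 0.14 with an estimated correlation). Genes of the Phosphatidylinositol signaling system fell in 65 of 77 and rose in 6 (adjusted p = 0.00216, and adjusted p = 0.3 with an estimated correlation). Systemic lupus erythematosus, a pathway made up in large part of histone genes, rose from DMSO to 8HQ_FAC in 41 of 60 and fell in 11 (adjusted p = 3.07e-07, and adjusted p = 0.0256 with an estimated correlation), and rose from FAC to 8HQ_FAC in 46 and fell in 6 (adjusted p = 9.05e-10, and adjusted p = 0.00849 with an estimated correlation). The list of replication-dependent histone genes lost its call in both comparisons with the length trend removed. Complement and coagulation cascades, largely proteins that the liver secretes, rose from FAC to 8HQ_FAC in 37 of 52 and fell in 9 (adjusted p = 1.86e-08, and adjusted p = 0.0307 with an estimated correlation). Antigen processing and presentation rose there in 24 of 38 and fell in 12 (adjusted p = 3.94e-05, and adjusted p = 0.0324 with an estimated correlation), and Lysosome in 53 of 105 with 34 lower (adjusted p = 0.000259, and adjusted p = 0.0382 with an estimated correlation). Staphylococcus aureus infection, Rheumatoid arthritis and Alcoholism were also called higher there with an estimated correlation (0.0324 each).

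With FAC alone, Glycolysis / Gluconeogenesis rose in 26 of 46 and fell in 7 (adjusted p = 0.000531, and adjusted p = 0.154 with an estimated correlation), and DNA replication fell in 23 of 35 and rose in 2 (adjusted p = 0.00234, and adjusted p = 0.19 with an estimated correlation). Valine, leucine and isoleucine degradation rose in 23 of 43 and fell in 5 (adjusted p = 0.00578, and adjusted p = 0.328 with an estimated correlation). With 8HQ alone, 0 pathways were called, and the lowest adjusted p was 0.0638, for Arrhythmogenic right ventricular cardiomyopathy and Hypertrophic cardiomyopathy.

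Most calls of 8HQ_FAC vs DMSO were lower. Lower depth of the 8HQ_FAC libraries predicted no fall among abundant genes, and the test set beforehand came out that way, with a median log2 change of 0.10 in 2987 genes of at least 20 FPKM. As the whole cause it is argued against by the 404 of them with the longest transcripts, which have the most reads per FPKM and had a median of -0.47. Transcript length met the test set for it (Spearman correlation -0.52, and -0.37 with the median transcript of each gene), so a length bias of the 8HQ_FAC libraries, such as from RNA length or integrity, may account for many of the lower calls. A scaling factor for each library moves all genes the same way. Alone it cannot give the median log2 changes of 0.24 in the shortest and -0.63 in the longest length bin. Its part in the lower calls cannot be told apart from that of length, since 63.3% of calls were higher after median centring and 15.7% with rescaling to equal sums. The 10.9% of tested genes called with at least 2-fold after centring say nothing on direction. An effect of the agents on long transcripts stays open too, as RNA integrity is not given in the sources used here.

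Blood cell transcripts were seen in the DMSO and 8HQ libraries and mostly not in those with FAC. Fewer reads in the FAC libraries are argued against for that group, as its mean relative depth was 1.002 times that of 8HQ. For the 8HQ_FAC libraries they are argued against because at least 11.6 list members would still be above 0 at their lowest depth, which is 3.6 above the highest number seen (8), with a binomial SD of 1.6. RNA or reads from other cells in the 6 libraries without FAC stay open as well: the lowest of these had 5 more leukocyte list members above 0 than the highest with FAC, but that is the pattern itself and no test of its origin. No biological explanation was tested.

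HIF targets were higher with FAC, at a median log2 change of 0.51. Iron raising the activity of the HIF prolyl hydroxylases would lower these genes, so by direction alone it is not the cause of the higher levels. This rests on the observed median, not on a further test. Handling that follows FAC, where the list lay 0.52 above all genes, cannot be told apart from an effect of FAC, since the blood cell transcripts split the libraries as FAC does. In 8HQ_FAC vs FAC, where both groups had FAC, 18 of 39 members were higher and 14 lower (adjusted p = 0.00887, and adjusted p = 0.0697 with an estimated correlation). In the interaction 17 were higher and 12 lower (adjusted p = 0.00664, and adjusted p = 0.0588 with an estimated correlation). Neither comparison tests FAC without 8HQ, and neither result was followed under the other scalings. A response of the cells to FAC by another route stays open.

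For the comparisons of 2 groups, the 6 libraries were split into 3 and 3 in all 10 ways, and in each comparison 1 of the 10, the real one, called as many genes. The real and the highest other counts were 9121 and 0 for 8HQ_FAC vs DMSO, 531 and 1 for 8HQ vs DMSO, 5848 and 0 for FAC vs DMSO, 8968 and 0 for 8HQ_FAC vs FAC, and 9139 and 0 for 8HQ_FAC vs 8HQ. These splits are too few for a share under 0.05.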
